A study of Mus musculus with 15 samples.

How the data were processed

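The starting data were the deposited counts, 1 HTSeq table per library with 52550 genes each. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to GRCm38 with TopHat2 and counted with HTSeq. Tool versions, strand setting and annotation release were not given in the sources used here. Per the labels, libraries were stranded mRNA libraries read single-end at 50 bp, from organoids of mice aged 8 to 12 weeks. No reads were realigned here.

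Symbols and positions came from GENCODE M21, which held 52403 of the gene IDs and 99.992% of the counts. The list member Gm15284 was the only one without a match. Library totals ran from 5774771 to 21386586 counts.

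The main analysis used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passed filterByExpr with the group as factor, leaving 16226. TMM factors ran from 0.925 to 1.044. A quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 15 libraries, with 10 residual degrees of freedom and a common biological coefficient of variation of 13.4%. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. The SE is the absolute log2 fold change divided by the square root of F. CPM values are TMM-normalised. The smallest exact two-sided p for 3 against 3 libraries is 0.1.

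The 7 planned comparisons were the Rnaseh2b knockout with the floxed control, the Xbp1 knockout with the floxed control, the Rnaseh2b Xbp1 knockout with the Rnaseh2b knockout, the Xbp1 knockout and the floxed control, the Rnaseh2b Trp53 knockout with the Rnaseh2b knockout, and the interaction of Rnaseh2b and Xbp1. Comparisons of the Rnaseh2b Trp53 knockout with the floxed control and of the Rnaseh2b knockout with the Xbp1 knockout were added after the data were seen.

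Of 24 gene lists, 22 were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. These were p53 targets, XBP1 secretory pathway and ERAD, ER chaperones of the ATF6 branch, ATF4 targets, IRE1 and its RNA substrates, interferon-stimulated genes, antigen presentation, S phase, G2 and mitosis, DNA repair, stem cell, Paneth, goblet, enteroendocrine, tuft, enterocyte, fetal-like, inflammation and NF-kB, NRF2 and glutathione, cholesterol biosynthesis, mTORC1 and non-epithelial genes. The lists of sex-linked genes and RNase H2 subunits were not tested as sets. Lists were written from general knowledge.

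Genes named in the text were 15 fixed genes, up to 8 with the largest rise and 8 with the largest fall that were called at a mean of at least 5 CPM without overlap of the groups, and up to 4 called members of each called list. Where a called list had no called member, 2 members are given as values. The comparisons, lists, naming rule and alternatives were fixed before the data were examined. Alternatives were other filters and normalisation, DESeq2 1.42.0, only the groups compared, a block by replicate letter, LW50 libraries alone and leaving out each library. Counts without chromosomes X and Y and limma voom with weights per group were added later. A fit without the 3 libraries under 11 M counts and the 9 libraries of the block check without the block were also added later.

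The pipeline was tested on simulated data with added changes. It recovered 89% of 2-fold changes in the design of the Rnaseh2b knockout with the floxed control and 68% for the interaction, with a false share of 4.6% and 4.7%. Apart from the added changes, all simulated libraries shared the mean and dispersion of each gene, and only genes above 5 CPM were changed. The unequal spread of the real groups and the split by title prefix were not simulated. These shares need not hold for the real calls. Reversal and similarity were compared with 100 simulated sets that share the same control libraries. Ano3 had no count in the Rnaseh2b Trp53 knockout and is given no fold there. Read-level checks, splice forms and the deleted exons were left out, since only gene counts were available.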

Results

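Messenger RNA was sequenced from 15 libraries of mouse small intestinal organoids, which are cultures of gut epithelium that keep stem cells and their differentiated offspring. The libraries fell into 5 genotype groups of 3. The floxed control carried floxed Rnaseh2b and Xbp1 alleles without deletion. The other groups were epithelial knockouts of Xbp1, Rnaseh2b, both Rnaseh2b and Xbp1, or both Rnaseh2b and Trp53, made through a Villin-driven Cre recombinase. Rnaseh2b encodes the B subunit of ribonuclease H2, which removes ribonucleotides from DNA. Xbp1 encodes a transcription factor of the unfolded protein response, and Trp53 encodes p53. Depth was 16.8 to 21.4 M (mega) counts per library in the floxed control, 10.2 to 19.8 M in the Xbp1 knockout, 5.77 to 15.1 M in the Rnaseh2b knockout, 10.6 to 17.5 M in the Rnaseh2b Xbp1 knockout and 13.55 to 15.8 M in the Rnaseh2b Trp53 knockout. Library titles of the first 3 of these groups began with LW50. In the Rnaseh2b Xbp1 knockout, libraries 1 and 4 carried LW45 and library A carried LW50, and titles of the Rnaseh2b Trp53 knockout had no such prefix. The labels gave n = 3 mice but did not say that each library came from a separate mouse. The p-values therefore measure the spread between these libraries, which may be technical. That spread was pooled over the 5 groups, with a biological coefficient of variation of 13.4%. Within single groups it ran from 3.5% in the Rnaseh2b Trp53 knockout to 22.6% in the Rnaseh2b Xbp1 knockout. The p-values are thus not based on the spread of the compared groups alone. Expression is given as library-scaled counts per M (CPM, mean ± SD over 3 libraries), and fold changes are on the log2 scale with their standard error (SE), from edgeR with Benjamini-Hochberg adjusted p over 16226 genes.

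The targeted genes were read in every library first. Rnaseh2b (ENSMUSG00000021932, GRCm38 chromosome 14, 62292589 to 62372992) stood at 17.96, 14.48 and 16.12 CPM in the floxed control and at 16.98, 13.76 and 15.04 CPM in the Xbp1 knockout. It was at 4.92, 6.91 and 5.33 CPM in the Rnaseh2b knockout, 6.36, 7.05 and 6.60 CPM in the Rnaseh2b Xbp1 knockout and 2.13, 1.70 and 1.07 CPM in the Rnaseh2b Trp53 knockout. Xbp1 (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893) averaged 283 ± 6.52 CPM in the floxed control, 71.8 ± 6.92 CPM in the Xbp1 knockout, 324 ± 24.1 CPM in the Rnaseh2b knockout, 163 ± 18.4 CPM in the Rnaseh2b Xbp1 knockout and 303 ± 6.96 CPM in the Rnaseh2b Trp53 knockout. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) averaged 10.9 ± 0.935 CPM in the Rnaseh2b Trp53 knockout and 89.4 to 105 CPM in the other groups. Counts at Trp53 can include reads shared with its pseudogene, and gene counts include exons outside the deleted parts. The Rnaseh2b Xbp1 knockout kept more Xbp1 RNA than the Xbp1 knockout, and whether deletion was complete there was not tested. Xist, the RNA that silences an X chromosome, averaged 957 ± 295 CPM in the floxed control and 880 ± 99.2 CPM in the Rnaseh2b Trp53 knockout. It averaged 0.858, 4.44 and 0.644 CPM in the Xbp1, Rnaseh2b and Rnaseh2b Xbp1 knockouts, where the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty averaged 37.2 to 113 CPM. The floxed control and the Rnaseh2b Trp53 knockout thus had the expression of females and the other 3 groups that of males. Every comparison between those sets of groups differed in sex as well as genotype. Of the list of RNase H2 subunits, only Rnaseh2b was called in any comparison against the floxed control.

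**Figure D1:**
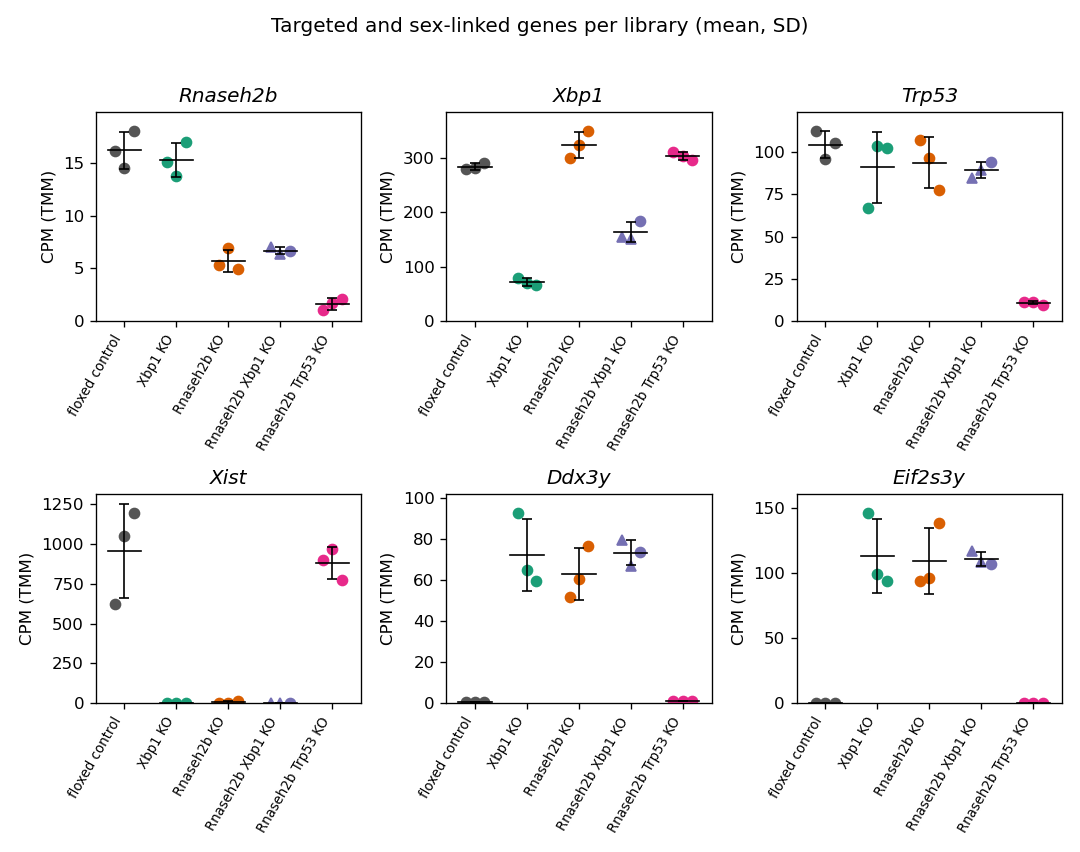
Expression of the targeted genes Rnaseh2b, Xbp1 and Trp53 and of the sex-linked genes Xist, Ddx3y and Eif2s3y, in CPM on the vertical axis, for each library of the 5 groups on the horizontal axis, with triangles for LW45 libraries and bars for the mean and SD. Xbp1 averaged 163 CPM in the Rnaseh2b Xbp1 knockout against 71.8 CPM in the Xbp1 knockout.

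The Rnaseh2b knockout was compared with the floxed control to ask what loss of RNase H2 changed in the epithelium. Genes that p53 is known to activate were higher. Eda2r, a receptor gene on chromosome X, stood at 34.6 ± 2.08 CPM against 8.02 ± 0.119 CPM, a log2 fold change of 2.10 (SE 0.18, adjusted p = 1.09e-05). Plk2, a kinase of the cell cycle, rose from 10.4 ± 0.229 to 26.8 ± 1.75 CPM, by 1.36 (SE 0.12). Ddit4l (ENSMUSG00000046818, chromosome 3, 137621612 to 137628333), an inhibitor of mTORC1, rose 5.59-fold from 1.70 ± 0.507 to 9.61 ± 1.43 CPM. Rnaseh2b itself fell by 1.48 (SE 0.18, adjusted p = 0.000588).

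Of the 34 p53 targets tested in this comparison, 9 rose and none fell, and 15 rose when adjusted over the list alone. The median change of the list was 0.33, with a camera adjusted p of 6.84e-19, and the adjusted p was 0.00656 with an estimated correlation. Zmat3, an RNA-binding protein, rose by 0.65 (SE 0.09) and Ccng1, cyclin G1, rose by 0.97 (SE 0.14), from 294 ± 25.0 to 579 ± 86.2 CPM. Cdkn1a, the p53-driven inhibitor of the cell cycle, was not called, at 306 ± 13.4 CPM against 287 ± 39.7 CPM, and neither was Mdm2, at 0.38 (SE 0.12, adjusted p = 0.209). No other list kept a call with an estimated correlation. Of 27 ATF4 targets, genes of the integrated stress response, 1 fell, and 3 fell when adjusted over the list alone. Their median was -0.26 (camera adjusted p = 8.99e-08, adjusted p = 0.223 with an estimated correlation). Of 13 antigen presentation genes 1 fell, and 4 fell when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 1.5e-05, adjusted p = 0.212 with an estimated correlation). That member was Psmb8, a subunit of the immunoproteasome, at 2.90 ± 0.301 against 6.31 ± 0.954 CPM, whose call ended without Rnaseh2b knockout C at -1.05.

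Cell type lists held almost no called members between the Rnaseh2b knockout and the floxed control. The 20 enterocyte markers had a median of 0.28 with none called and 4 higher when adjusted over the list alone (camera adjusted p = 0.000356, adjusted p = 0.59 with an estimated correlation). Their summed expression was 11840 CPM in Rnaseh2b knockout A, the library of 5.77 M counts, against 7172 and 7438 CPM in B and C. The 13 Paneth cell markers had a median of -0.28 with none called (camera adjusted p = 0.0367, adjusted p = 0.63 with an estimated correlation). Among them the lysozyme gene Lyz1 stood at 201 ± 18.3 against 440 ± 23.2 CPM. Its test used the spread pooled over all groups, and Lyz1 stood at 94 ± 74.3 CPM in the Rnaseh2b Xbp1 knockout. The missing call is thus no evidence of equal Lyz1 levels. The 24 DNA repair genes had a median of 0.11 with none called (camera adjusted p = 0.0424, adjusted p = 0.63 with an estimated correlation). The 6 tested RNAs of the list of IRE1 and its substrates had a median of -0.24 with none called and 2 lower when adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.212 with an estimated correlation). The 33 interferon-stimulated genes had a median of -0.31 with none called and 1 higher when adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.772 with an estimated correlation). That list's call also ended without floxed control B or C at medians of -0.24 and -0.20, and without Rnaseh2b knockout B or C at -0.26 and -0.08. The 36 XBP1 secretory pathway genes had a median of -0.04 with none called and 1 lower when adjusted over the list alone (camera adjusted p = 0.385).

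In all, edgeR called 135 genes between the Rnaseh2b knockout and the floxed control, 91 higher and 44 lower, and 122 of them lay outside chromosomes X and Y. Outside the lists, Mcam, an adhesion molecule, rose by 2.61 (SE 0.18) to 14.5 ± 2.24 CPM, and Camk2b, a kinase subunit, rose by 2.50 (SE 0.19) to 17.9 ± 1.52 CPM. Pttg1, securin, fell by 1.87 (SE 0.14) to 9.48 ± 1.42 CPM, and Emid1, an extracellular matrix gene, fell by 1.64 (SE 0.25). Camk2b and Emid1 lie 0.449 and 0.414 Mb from Xbp1, whose floxed allele the labels give to the floxed control but not to the Rnaseh2b knockout. Without 1 library the count moved by more than 1.5 times, to 78, 76 and 72 without floxed control A, B and C and to 76 and 73 without Rnaseh2b knockout B and C.

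The Xbp1 knockout was compared with the floxed control to ask what loss of Xbp1 alone changed. Genes of the secretory pathway fell. Xbp1 fell by 1.98 (SE 0.10, adjusted p = 5.26e-09). Fkbp11, a prolyl isomerase of the endoplasmic reticulum (ER), fell by 1.81 (SE 0.12) from 18.6 ± 1.76 to 5.26 ± 0.545 CPM, and Pdia6, a disulfide isomerase, fell 2.00-fold from 338 ± 9.23 to 169 ± 11.1 CPM. Hspa5, the main ER chaperone, fell by 0.74 (SE 0.10, adjusted p = 0.000491) from 900 ± 43.1 to 538 ± 54.5 CPM. The p53 target Cdkn1a rose by 0.57 (SE 0.10, adjusted p = 0.00311) from 287 ± 39.7 to 425 ± 35.3 CPM.

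Of the 36 XBP1 secretory pathway genes, 22 fell and none rose in the Xbp1 knockout, and 27 fell when adjusted over the list alone. The median was -0.50 (camera adjusted p = 5.9e-40), and the adjusted p was 0.000284 with an estimated correlation. Hyou1, an ER chaperone, fell by 1.13 (SE 0.10), and Sec61a1, a subunit of the translocation channel, fell by 1.03 (SE 0.09). Of 10 ER chaperones of the ATF6 branch, 4 fell, and 7 fell when adjusted over the list alone, with a median of -0.35 (camera adjusted p = 1.64e-10, adjusted p = 0.00203 with an estimated correlation). Among them Manf fell by 1.17 (SE 0.12), Creld2 fell by 0.85 (SE 0.13) and Pdia4 fell by 0.57 (SE 0.09). Nucb2, a calcium-binding protein, and Bhlha15, a transcription factor of secretory cells, changed by -2.10 (SE 0.22) and -1.89 (SE 0.18).

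Of the 34 p53 targets, 9 rose and none fell in the Xbp1 knockout, and 12 rose when adjusted over the list alone, and Plk2 rose by 0.62 (SE 0.12). The camera adjusted p was 2.39e-06, and the adjusted p was 0.089 with an estimated correlation. Of the 20 enterocyte markers, 10 rose, and 16 rose when adjusted over the list alone, with a median of 0.95 (camera adjusted p = 1.8e-12, adjusted p = 0.114 with an estimated correlation). Apoc3, an apolipoprotein, rose by 1.81 (SE 0.30) from 28.9 ± 13.4 to 101 ± 14.4 CPM. Summed enterocyte markers reached 21120 CPM in Xbp1 knockout C, the shallowest library of the group, against 13540 and 13730 CPM in A and B. Goblet cell markers moved both ways, with 3 of 18 higher and 3 lower, and 8 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0086, adjusted p = 0.339 with an estimated correlation). Agr2, a disulfide isomerase needed for mucin, fell by 1.64 (SE 0.19), while the lectin Zg16 rose by 3.96 (SE 0.56), Ccl6 rose by 1.61 (SE 0.20) and Clca1 rose by 1.52 (SE 0.28). Of 14 inflammation and NF-kB targets 3 rose, and 6 rose when adjusted over the list alone (camera adjusted p = 2.31e-05, adjusted p = 0.0754 with an estimated correlation). They included Duox2 and Duoxa2, an oxidase and its maturation factor, which rose by 2.46 (SE 0.44) and 2.83 (SE 0.36).

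The other lists called in the Xbp1 knockout went down, and each call was lost with an estimated correlation. Of 27 ATF4 targets 6 fell, and 13 fell when adjusted over the list alone, with a median of -0.35 (camera adjusted p = 5.18e-07, adjusted p = 0.173 with an estimated correlation). Of 23 S phase genes 4 fell, and 7 fell when adjusted over the list alone (camera adjusted p = 1.44e-06, adjusted p = 0.173 with an estimated correlation). Of 33 interferon-stimulated genes 3 fell, and 8 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000345, adjusted p = 0.366 with an estimated correlation). Lists of G2 and mitosis, DNA repair and stem cell markers had 2, 1 and 0 members lower, or 3, 1 and 0 when adjusted over the list alone, and adjusted p of 0.292, 0.33 and 0.27 with an estimated correlation. Outside the lists, Mid1, an X-linked ubiquitin ligase, rose by 3.09 (SE 0.22) from 2.99 ± 0.407 to 25.6 ± 4.65 CPM. Wdfy1, an endosomal protein, fell by 2.54 (SE 0.20) from 110 ± 7.86 to 19.2 ± 4.16 CPM, and the hormone gene Ghrl fell by 2.35 (SE 0.25). In all, 888 genes were called by edgeR, 544 higher and 344 lower. Without 1 library the count was 313 and 308 without floxed control A and C, and 531 and 376 without Xbp1 knockout B and C.

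The Rnaseh2b Xbp1 knockout was compared with the Rnaseh2b knockout to ask what loss of Xbp1 added where Rnaseh2b was already deleted. These groups were of the same sex. Secretory, mitotic, DNA repair and stem cell genes fell. Pdia6 (ENSMUSG00000020571, chromosome 12, 17266545 to 17284770) fell by 0.67 (SE 0.07, adjusted p = 8.47e-05) from 317 ± 13.0 to 200 ± 10.6 CPM, and Itln1, a lectin of Paneth cells, fell by 1.66 (SE 0.12) from 649 ± 97.6 to 206 ± 14.5 CPM. Olfm4, a marker of crypt stem cells, fell by 1.71 (SE 0.23) from 287 ± 5.91 to 87.8 ± 29.2 CPM. Gstm1, a glutathione transferase with close paralogs, rose by 1.96 (SE 0.23) from 261 ± 41.9 to 1010 ± 269 CPM.

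Of the 36 XBP1 secretory pathway genes, 23 fell and none rose, and 25 fell when adjusted over the list alone. The median was -0.40 (camera adjusted p = 5.83e-14, adjusted p = 0.0121 with an estimated correlation), and among LW50 libraries alone it was -0.42. Pdia5 fell by 1.26 (SE 0.15), Ostc fell by 0.68 (SE 0.09) and Spcs2 fell by 0.64 (SE 0.09). Of 10 ER chaperones 5 fell, and 7 fell when adjusted over the list alone (camera adjusted p = 0.000382, adjusted p = 0.0319 with an estimated correlation), and Pdia4 fell by 0.47 (SE 0.09). The 34 p53 targets as a list were not called, with 2 higher, 2 lower and a median of -0.10 (camera adjusted p = 0.484), and the LW50 libraries alone gave -0.01. The targets Plk3 and Cdkn1a rose by 1.13 (SE 0.21) and 0.35 (SE 0.10), and Cdkn1a went from 306 ± 13.4 to 389 ± 14.9 CPM but was not called in 5 of 15 alternatives. Zfp365 fell from 3.69 ± 0.239 to 1.15 ± 0.769 CPM and Btg2 from 134 ± 7.25 to 110 ± 14.1 CPM. These targets were not called in 5 and 8 of 15 alternatives. Ddit4l, of the mTORC1 list, fell by 1.07 (SE 0.21) to 4.59 ± 0.477 CPM and stood at -0.93, not called, among LW50 libraries alone. Ccng1 was not called, at 466 ± 50.3 against 579 ± 86.2 CPM.

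Proliferation and stem cell genes were lower in the Rnaseh2b Xbp1 knockout than in the Rnaseh2b knockout. Of 23 genes of G2 and mitosis 18 fell, and 21 fell when adjusted over the list alone (camera adjusted p = 4.46e-15, adjusted p = 0.0319 with an estimated correlation). Aurka and Bub1b, mitotic kinases, changed by -0.55 (SE 0.07) and -0.52 (SE 0.07), and by -0.50 and -0.54 among LW50 libraries alone. Of 24 DNA repair genes 15 fell, and 18 fell when adjusted over the list alone (camera adjusted p = 5.95e-12, adjusted p = 0.0319 with an estimated correlation), and Fanci fell by 0.78 (SE 0.11) and the checkpoint kinase Chek2 fell by 0.53 (SE 0.09). Of 17 stem cell markers 8 fell, and 10 fell when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 4.05e-08, adjusted p = 0.0319 with an estimated correlation). Smoc2, a niche matrix gene, fell by 1.00 (SE 0.14), while Lgr5 was not called at -0.42 (SE 0.16, adjusted p = 0.0764) but was called at -0.95 among LW50 libraries alone (adjusted p = 0.00827). Of 23 S phase genes 13 fell, and 16 fell when adjusted over the list alone (camera adjusted p = 1.25e-10, adjusted p = 0.0634 with an estimated correlation), and Rrm1 fell by 0.61 (SE 0.08) and Cdc45 fell by 0.75 (SE 0.11).

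Of 13 Paneth cell markers 7 fell, and 8 fell when adjusted over the list alone, with a median of -1.40 (camera adjusted p = 1.28e-07, adjusted p = 0.0634 with an estimated correlation). Their sum was 331 and 396 CPM in the LW45 libraries, 742 CPM in the LW50 library and 1558 to 1703 CPM in the Rnaseh2b knockout. Of 17 NRF2 targets and glutathione genes, 10 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.99e-09, adjusted p = 0.0918 with an estimated correlation). Nqo1, a quinone reductase, rose by 1.08 (SE 0.16). The list summed to 7145 and 6308 CPM in the LW45 libraries and to 4384 CPM in the LW50 library, against 2833 to 3348 CPM in the Rnaseh2b knockout. Of 13 antigen presentation genes 4 rose either way of adjusting (camera adjusted p = 0.0129, adjusted p = 0.387 with an estimated correlation), among them the peptide transporter Tap2 by 0.86 (SE 0.13). The summed list was no higher, at 1148 to 1204 CPM against 1195 to 1266 CPM. Of 20 enterocyte markers 5 rose either way (camera adjusted p = 0.0144, adjusted p = 0.605 with an estimated correlation), and Treh, trehalase, rose by 0.93 (SE 0.14). Of 18 goblet cell markers 3 fell, and 6 fell when adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.524 with an estimated correlation), and Agr2 fell by 1.22 (SE 0.19) but was at -0.73 and not called among LW50 libraries alone.

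Outside the lists, Mid1 rose by 3.69 (SE 0.24), Sardh, a mitochondrial enzyme of sarcosine breakdown, rose by 2.32 (SE 0.24) and the nuclear RNA Neat1 rose by 2.41 (SE 0.45) from 143 ± 59.1 to 763 ± 96.3 CPM. Mitochondrial genes held 1.68 to 1.83% of counts in the Rnaseh2b Xbp1 knockout, 0.826 to 1.43% in the Rnaseh2b knockout, 1.40 to 1.66% in the floxed control and 1.38 to 1.71% in the Xbp1 knockout, and RNA quality was not measured. Plod2, a lysyl hydroxylase, fell by 3.07 (SE 0.25) from 21.3 ± 2.48 to 2.56 ± 0.694 CPM. Adcy1, an adenylate cyclase 1.54 Mb from Xbp1, fell by 2.65 (SE 0.37), and Emid1 rose by 2.25 (SE 0.25). In all, edgeR called 2769 genes, 1596 higher and 1173 lower. Among LW50 libraries alone, which leave 1 Rnaseh2b Xbp1 knockout library assumed to vary like the other groups, 1481 were called and 811 of these were shared. The count was 1532 without Rnaseh2b knockout B, 1787 without Rnaseh2b Xbp1 knockout 1 and 795 when only these groups were fitted.

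Whether loss of Xbp1 moved the genes of the Rnaseh2b knockout back was counted next. Of the 135 genes called between the Rnaseh2b knockout and the floxed control, 103 (76.3%) had a change of opposite sign from the Rnaseh2b knockout to the Rnaseh2b Xbp1 knockout. The contrasts share the Rnaseh2b knockout libraries with opposite sign, and 100 simulated sets without an effect of Xbp1 gave a median share of 73.4%, from 68.1% to 77.9%. Of the 135, 49 were called in the opposite direction, 30 of 91 raised genes and 19 of 44 lowered ones, and 5 were called in the same direction. Independent lists give 6.58 raised genes and 4.33 lowered genes called in the opposite direction, and part of the excess may come from the shared libraries. The simulated sets, which held no effect of Xbp1 and had 549 to 729 genes called in the first contrast, could give almost no such calls and are no measure of them. Ddit4l was among the raised genes that fell. Per the labels, the floxed control and the Rnaseh2b Xbp1 knockout carried the floxed Xbp1 allele and the Rnaseh2b knockout did not. Adcy1, Camk2b, Emid1 and Ap1b1, near Xbp1, were among the genes called in the opposite direction. Their changes were 2.7, 2.5, -1.64 and -0.52, and then -2.65, -1.94, 2.25 and 0.52. For such genes the allele and loss of Xbp1 cannot be told apart. Xist was not called between the Rnaseh2b Xbp1 knockout and the Rnaseh2b knockout.

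The Rnaseh2b Xbp1 knockout was compared with the Xbp1 knockout, of the same sex, to ask what loss of Rnaseh2b added where Xbp1 was already deleted. Rnaseh2b fell by 1.19 (SE 0.18, adjusted p = 0.000757), and the Xbp1 RNA rose by 1.19 (SE 0.09, adjusted p = 1.3e-05). The groups thus also differed in the Xbp1 RNA left, at 163 ± 18.4 against 71.8 ± 6.92 CPM. Its part in the changes below, such as those of secretory pathway genes, was not tested. Olfm4 fell by 2.68 (SE 0.24) from 562 ± 171 to 87.8 ± 29.2 CPM. Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868) fell by 2.51 (SE 0.39) from 531 ± 46.1 to 94.0 ± 74.3 CPM, and was at -1.55 among LW50 libraries alone. The p53 target Eda2r rose by 1.29 (SE 0.18, adjusted p = 0.00047) from 13.3 ± 1.66 to 32.1 ± 7.18 CPM.

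As a list, the 34 p53 targets were not called between the Rnaseh2b Xbp1 knockout and the Xbp1 knockout, with 7 higher, 2 lower and a median of 0.05, or 8 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.288). Of 13 Paneth cell markers 7 fell, with a median of -1.97 (camera adjusted p = 4.35e-07, adjusted p = 0.268 with an estimated correlation). Of 23 genes of G2 and mitosis 13 fell (camera adjusted p = 1.98e-06, adjusted p = 0.268 with an estimated correlation), and of 18 goblet cell markers 10 fell and 2 rose (camera adjusted p = 9.6e-06, adjusted p = 0.268 with an estimated correlation). Stem cell markers had 6 lower and 1 higher, or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.268 with an estimated correlation). DNA repair genes had 5 lower and 1 higher, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.503 with an estimated correlation). Among LW50 libraries alone Kif23, Aurka, Bub1b and Top2a were at -0.28, -0.29, -0.35 and -0.39. There Chek2, Chek1, Fanci and Fanca were at -0.41, -0.24, -0.31 and 0.41. Olfm4, Smoc2, Axin2 and Rgmb were at -2.22, -0.29, -0.65 and -0.46, and Klk1, Ccl6, Galnt12 and Spink4 at -1.07, -1.63, -0.64 and -0.84. Of 17 NRF2 targets 10 rose either way of adjusting (camera adjusted p = 0.000441, adjusted p = 0.398 with an estimated correlation). The list summed to 7145 and 6308 CPM in the LW45 libraries, 4384 CPM in the LW50 library and 3236 to 4333 CPM in the Xbp1 knockout. Among LW50 libraries alone Gstm1, Nqo1, Gsta1 and Gclc were at 0.65, 0.78, 0.48 and 0.28 and not called. Of 33 interferon-stimulated genes 12 rose and 1 fell, with a median of 0.59 (camera adjusted p = 0.00161, adjusted p = 0.539 with an estimated correlation), and the list summed to 1161 and 1232 CPM in the LW45 libraries, 872 CPM in the LW50 library and 730 to 772 CPM in the Xbp1 knockout. XBP1 secretory pathway genes had 10 higher and 1 lower, or 11 and 2 when adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.398 with an estimated correlation). Among LW50 libraries alone Fkbp11, Hyou1, Sec61a1, Dnajb11 and Manf were at 0.79, 0.48, 0.42, 0.29 and 0.50 and not called. Inflammation and NF-kB targets had 3 lower and 2 higher, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.305 with an estimated correlation), and Duoxa2 fell by 2.60 (SE 0.37) and was at -1.49, not called, among LW50 libraries alone.

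Among single genes, Wdfy1 rose by 2.50 (SE 0.20) from 19.2 ± 4.16 to 107 ± 32.0 CPM, Sardh rose by 2.34 (SE 0.23) and Ghrl rose by 1.64 (SE 0.25). Kcnf1, a potassium channel subunit, fell by 2.47 (SE 0.25), and Bex1 fell by 2.48 (SE 0.32). In all, edgeR called 3233 genes, 1809 higher and 1424 lower. Fitting only the groups compared gave 235, and the LW50 libraries alone gave 175, of which 112 were shared. The count was 1479, 1437 and 5353 without Rnaseh2b Xbp1 knockout 1, 4 and A.

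The Rnaseh2b Xbp1 knockout was compared with the floxed control to measure both deletions together. Rnaseh2b fell by 1.28 (SE 0.18) and Xbp1 fell by 0.79 (SE 0.09, adjusted p = 0.000126). The p53 targets Trp53inp1 and Ccng1 rose by 1.20 (SE 0.20) and 0.66 (SE 0.14), and Cdkn1a rose by 0.44 (SE 0.10) to 389 ± 14.9 CPM, at 0.50 and not called among LW50 libraries alone. Itln1 fell by 1.97 (SE 0.12) from 807 ± 53.3 to 206 ± 14.5 CPM, and Olfm4 fell by 2.26 (SE 0.23). Hspa5 fell by 0.43 (SE 0.10) and Atf3, a stress-response transcription factor, fell by 1.05 (SE 0.13).

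Lists called with an estimated correlation numbered 6 in this comparison. Of 34 p53 targets 12 rose, and 14 rose when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 7.15e-08, adjusted p = 0.0309 with an estimated correlation). Of 36 XBP1 secretory pathway genes 22 fell, with a median of -0.43 (camera adjusted p = 4.05e-17, adjusted p = 0.00612 with an estimated correlation), and 6 of 10 ER chaperones fell (adjusted p = 0.0203 with an estimated correlation). Of 23 genes of G2 and mitosis 20 fell, of 17 stem cell markers 9 fell and of 13 Paneth cell markers 7 fell, each with an adjusted p of 0.0203 with an estimated correlation. Calls without that support were those of ATF4 targets with 11 of 27 lower (adjusted p = 0.09 with an estimated correlation) and S phase with 11 of 23 lower (adjusted p = 0.09 with an estimated correlation). Adjusted over their lists alone, 26 secretory pathway genes, 8 chaperones, 22 mitotic genes, 12 stem cell markers and 8 Paneth cell markers fell. DNA repair had 11 of 24 lower (adjusted p = 0.0805 with an estimated correlation), enterocyte markers 9 of 20 higher (adjusted p = 0.157 with an estimated correlation), NRF2 targets 10 of 17 higher (adjusted p = 0.111 with an estimated correlation) and goblet cell markers 7 of 18 lower and 3 higher (adjusted p = 0.456 with an estimated correlation). In all, edgeR called 2477 genes, 1411 higher and 1066 lower, and 809 among LW50 libraries alone, of which 407 were shared. The count was 1467, 1577 and 1231 without floxed control A, B and C, 1447, 1559 and 4292 without Rnaseh2b Xbp1 knockout 1, 4 and A, and 1300 when only these groups were fitted.

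**Figure D2:**
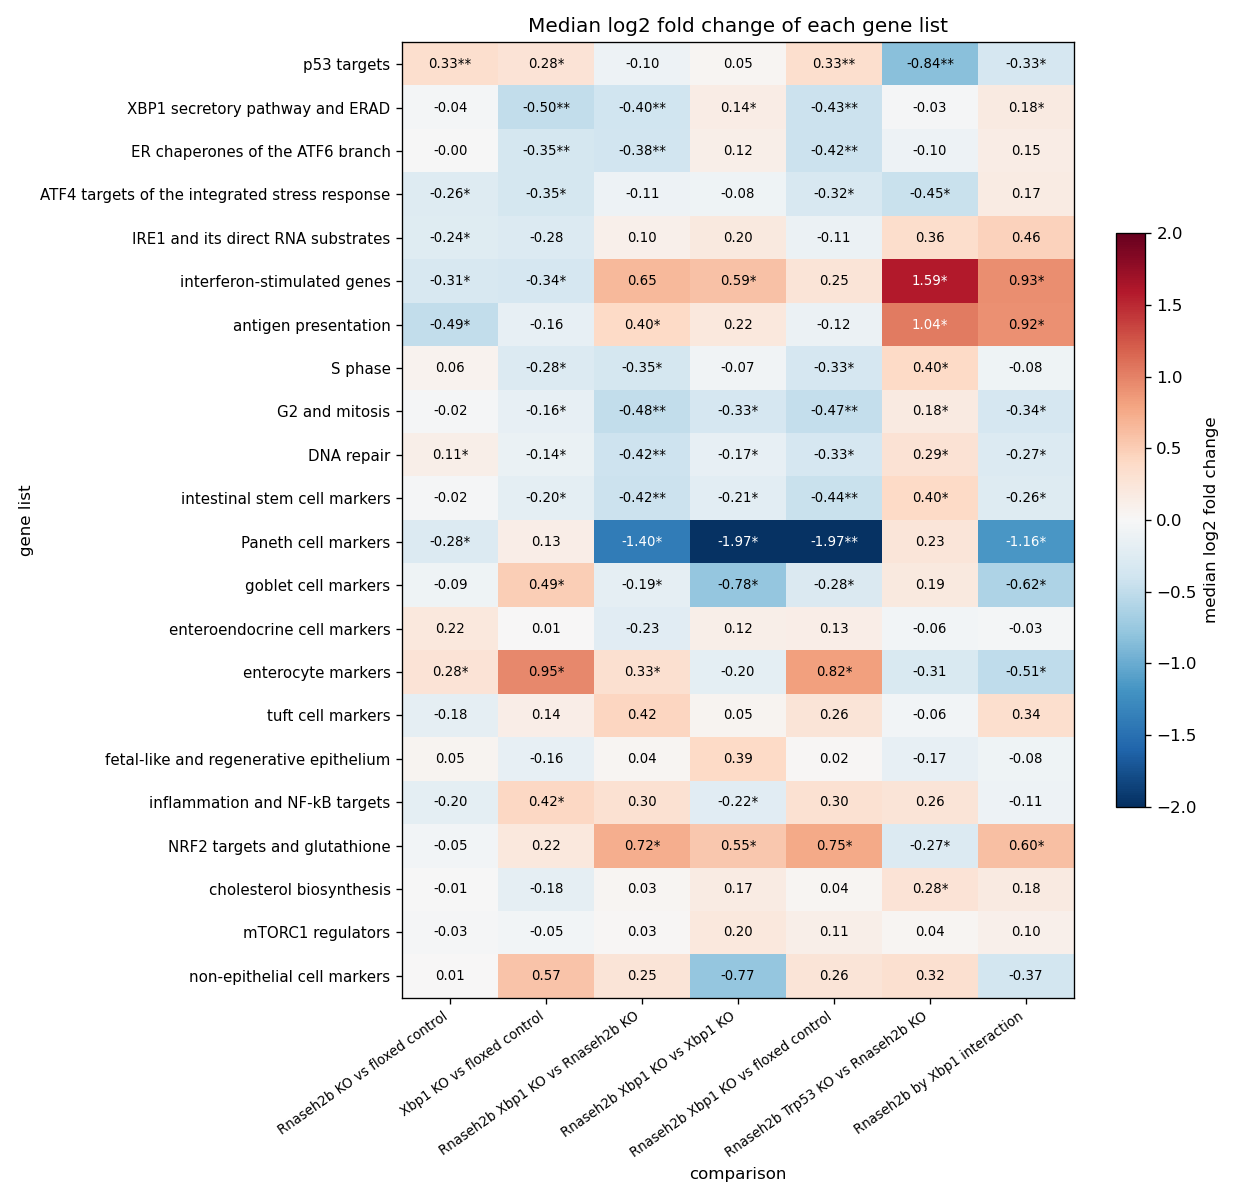
Median log2 fold change of each of the 22 tested gene lists on the vertical axis in each of the 7 comparisons on the horizontal axis, where 1 asterisk marks a camera adjusted p under 0.05 and a pair of asterisks a call kept with an estimated correlation. The p53 list had medians of 0.33 in the Rnaseh2b knockout against the floxed control and -0.84 in the Rnaseh2b Trp53 knockout against the Rnaseh2b knockout.

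The Rnaseh2b Trp53 knockout was compared with the Rnaseh2b knockout to ask what depended on p53 where Rnaseh2b was deleted. Genes activated by p53 fell. Interferon-stimulated genes rose, but the list had an adjusted p of 0.0631 with an estimated correlation. Trp53 fell by 3.11 (SE 0.17, adjusted p = 8.47e-09), Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) fell by 2.15 (SE 0.10, adjusted p = 2.51e-09) from 306 ± 13.4 to 68.8 ± 3.05 CPM, and Ccng1 fell by 2.80 (SE 0.15) from 579 ± 86.2 to 83.2 ± 3.97 CPM. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), a ubiquitin-like protein induced by interferon, rose by 3.23 (SE 0.43, adjusted p = 0.000176) from 1.04 ± 0.0756 to 9.79 ± 0.685 CPM. Rnaseh2b was also lower than in the Rnaseh2b knockout, by 1.81 (SE 0.22).

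Of 34 p53 targets 24 fell and none rose, and 28 fell when adjusted over the list alone, with a median of -0.84 (camera adjusted p = 1.06e-59, adjusted p = 4.93e-05 with an estimated correlation). Eda2r fell from 34.6 ± 2.08 to 0.203 ± 0.196 CPM, Phlda3 fell by 5.44 (SE 0.29), Zmat3 fell by 2.41 (SE 0.10) and Mdm2 fell by 0.81 (SE 0.12). Ddit4l, of the mTORC1 list, fell by 3.84 (SE 0.26). No other list kept its call with an estimated correlation. Of 33 interferon-stimulated genes 26 rose and 1 fell, and 28 rose and 1 fell when adjusted over the list alone, with a median of 1.59 (camera adjusted p = 1.15e-20, adjusted p = 0.0631 with an estimated correlation). Ifitm3, a membrane protein that blocks viral entry, rose by 1.95 (SE 0.18) and Xaf1 by 4.01 (SE 0.39). The chemokine Cxcl10 rose by 3.70 (SE 0.48) from only 0.348 CPM, and Rsad2, viperin, by 3.80 (SE 0.50) from 0.851 CPM. Xaf1 lies near Trp53 on chromosome 11, starting at 72301629. Whether sequence carried with the Trp53 allele sets its level was not tested. Within 10 Mb of Trp53, 65 of 299 genes were called where 53 would fall by chance (Fisher's exact p = 0.0656). Of 13 antigen presentation genes 10 rose, with a median of 1.04 (camera adjusted p = 6.16e-08, adjusted p = 0.0631 with an estimated correlation), and Psmb8 rose by 2.00 (SE 0.19) and Tap2 rose by 0.82 (SE 0.13). Of 27 ATF4 targets 16 fell, or 18 when adjusted over the list alone, with a median of -0.45 (camera adjusted p = 5.15e-13, adjusted p = 0.0631 with an estimated correlation). Chac1, which degrades glutathione, fell by 1.99 (SE 0.22), and Ddit3, the CHOP transcription factor, fell by 1.05 (SE 0.19).

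Some stem cell and proliferation genes were higher in the Rnaseh2b Trp53 knockout than in the Rnaseh2b knockout. Of 17 stem cell markers 8 rose, or 9 when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 1.47e-05, adjusted p = 0.0631 with an estimated correlation), and Olfm4 rose by 1.60 (SE 0.23), Ascl2 rose by 1.48 (SE 0.28) and Axin2 rose by 0.91 (SE 0.14). Of 23 S phase genes 14 rose, or 15 with 1 lower when adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.249 with an estimated correlation), and Rrm2 rose by 0.48 (SE 0.08). Of 24 DNA repair genes 9 rose and 1 fell, or 11 and 2 when adjusted over the list alone (camera adjusted p = 0.000524, adjusted p = 0.327 with an estimated correlation), and Pole rose by 0.62 (SE 0.09), and of 23 genes of G2 and mitosis 6 rose (camera adjusted p = 0.00311, adjusted p = 0.406 with an estimated correlation). Of 18 cholesterol biosynthesis genes 3 rose (camera adjusted p = 0.00642, adjusted p = 0.47 with an estimated correlation), and Hmgcr, the rate-limiting reductase, rose by 0.51 (SE 0.09). Of 17 NRF2 targets 4 fell (camera adjusted p = 0.0465, adjusted p = 0.63 with an estimated correlation), and Hmox1 fell by 0.90 (SE 0.11). Lyz1 rose by 1.68 (SE 0.37), and the endocrine progenitor genes Neurog3 and Insm1 rose by 1.54 (SE 0.22) and 1.39 (SE 0.23), while Areg, an EGF-family ligand, fell by 2.11 (SE 0.23).

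In all, edgeR called 2838 genes between the Rnaseh2b Trp53 knockout and the Rnaseh2b knockout, 1401 higher and 1437 lower, and 2748 lay outside chromosomes X and Y. The count was 1717 without Rnaseh2b knockout B and 1514, 1542 and 1679 without Rnaseh2b Trp53 knockout 1, 2 and 3. The groups differed in sex and in title prefix, and no library of another genotype shared the series of the Rnaseh2b Trp53 knockout, so genotype and series cannot be told apart. The non-epithelial marker Ptprc, a leukocyte antigen, averaged 0.0608 CPM in the Rnaseh2b Trp53 knockout.

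The changes that followed loss of Xbp1 and loss of Trp53 on the Rnaseh2b knockout background were compared across genes, which are not independent replicates. Pearson's r was 0.311 and Spearman's rho 0.285, against simulated medians of 0.543 and 0.488 where neither group differed from the shared Rnaseh2b knockout libraries. The covariance was 0.117 against a simulated 0.0421, a difference of 0.0752. Genes higher in both numbered 323 where independent lists give 138, genes lower in both 237 where independent lists give 104, and genes moving apart 91 and 142 where independent lists give 141 and 101. The simulated sets held no effects, with at most 1 gene called per direction in either comparison, and are no measure of shared calls. Part of the excess over independent lists may come from the shared controls, and 3 control libraries are too few to split. Atf3 fell in both comparisons, with changes of -0.91 (SE 0.14) and -1.30 (SE 0.14), and Tap2 rose in both. Olfm4 fell with loss of Xbp1 and rose with loss of Trp53.

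The interaction asked whether the effect of Xbp1 loss differed with the state of Rnaseh2b, as the change from the Rnaseh2b knockout to the Rnaseh2b Xbp1 knockout minus the change from the floxed control to the Xbp1 knockout. Xbp1 itself had an interaction of 0.99 (SE 0.13, adjusted p = 0.00143), since its RNA changed by -0.99 in the first change and -1.98 in the second. Loss of Xbp1 RNA was thus unequal, and the term cannot separate this from a dependence on Rnaseh2b. Fkbp11 had an interaction of 1.32 (SE 0.17) and Wdfy1 of 2.44 (SE 0.27), at 1.27 and 1.85 among LW50 libraries alone. Ddit4l had an interaction of -1.60 (SE 0.32, adjusted p = 0.0151), and Isg15 of 3.40 (SE 0.66, adjusted p = 0.0142), both not called among LW50 libraries alone at -1.45 and 2.72.

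As lists, p53 targets had a median interaction of -0.33, with 1 higher and 2 lower, and with 1 higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.000142, adjusted p = 0.24 with an estimated correlation). Interferon-stimulated genes had 7 of 33 higher, or 15 with 1 lower when adjusted over the list alone (camera adjusted p = 7.11e-05, adjusted p = 0.331 with an estimated correlation), antigen presentation 2 of 13 higher (adjusted p = 0.24 with an estimated correlation) and NRF2 targets 4 of 17 higher (adjusted p = 0.303 with an estimated correlation). XBP1 secretory pathway genes had 3 of 36 higher, or 8 when adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). G2 and mitosis had 4 of 23 lower, DNA repair 2 of 24, stem cell markers 2 of 17, Paneth cell markers 1 of 13 and goblet cell markers 4 of 18, each with adjusted p = 0.24 with an estimated correlation. Adjusted over the list alone, these had 11, 6, 2, 4 and 7 lower. Enterocyte markers had none called (camera adjusted p = 0.00416, adjusted p = 0.47 with an estimated correlation).

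In all, edgeR called 752 interactions, 461 positive and 291 negative, and 96 among LW50 libraries alone, of which 52 were shared. The term compares groups of both sexes, so that Xist and the Y-linked genes were called, and 715 lay outside chromosomes X and Y. The count was 309, 248 and 422 without floxed control A, B and C, 365 without Xbp1 knockout A, 386 and 200 without Rnaseh2b knockout A and B, and 246, 365 and 2993 without Rnaseh2b Xbp1 knockout 1, 4 and A. With only its 4 groups fitted it was 187.

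Lists without a call in any planned comparison were those of enteroendocrine, tuft, fetal-like, mTORC1 and non-epithelial genes. Between the Rnaseh2b knockout and the floxed control the 19 enteroendocrine markers had a median of 0.22 (camera adjusted p = 0.0524), the 10 tuft cell markers of -0.18 (camera adjusted p = 0.26) and the 14 fetal-like genes of 0.05 (camera adjusted p = 0.237), with 1 fetal-like gene higher. The 12 mTORC1 regulators had a median of -0.03, a mean of 0.13 and an upward test (camera adjusted p = 0.254), and 1 of them, Ddit4l, was higher. Of 21 non-epithelial markers only 5 were expressed enough to test, with a median of 0.01, a mean of -0.25 and a downward test (camera adjusted p = 0.56). Goblet cell markers differed in the same way there, with a median of -0.09 and a mean of 0.11 (camera adjusted p = 0.911). The sex-linked list had 4 genes higher and 1 lower in each of the 3 comparisons of males with the floxed control.

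**Figure D3:**
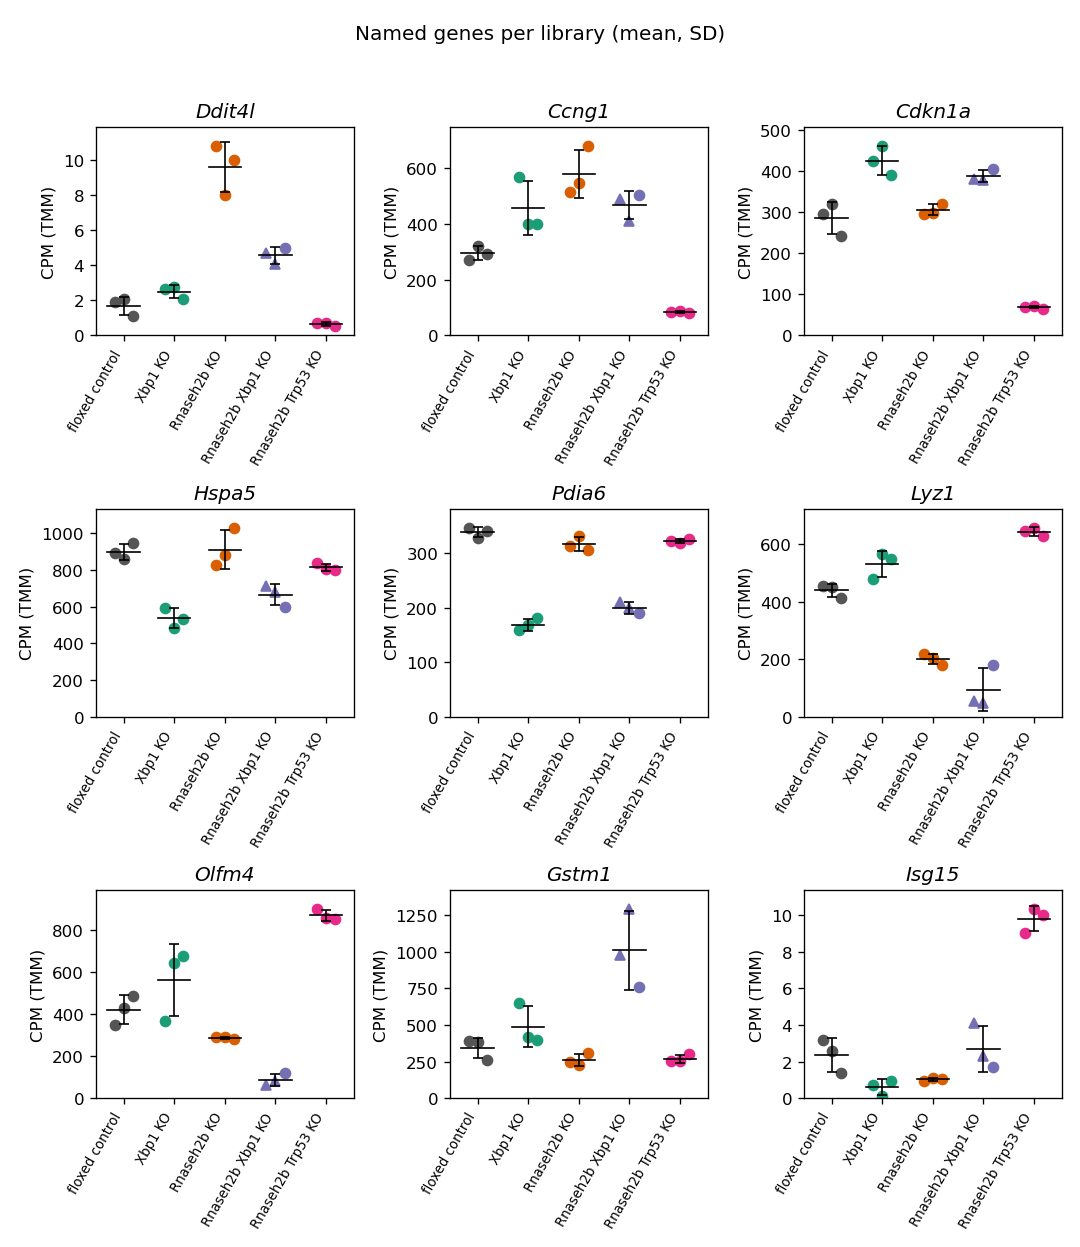
Expression of Ddit4l, Ccng1, Cdkn1a, Hspa5, Pdia6, Lyz1, Olfm4, Gstm1 and Isg15 in CPM on the vertical axis for each library of the 5 groups on the horizontal axis, with triangles for LW45 libraries and bars for the mean and SD. Ddit4l averaged 9.61 CPM in the Rnaseh2b knockout and 0.662 CPM in the Rnaseh2b Trp53 knockout.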

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

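The tests of sex, of library A, of mislabelling, of depth, of the prefix batch and of the separate series were chosen only after the result was seen, and that of immune cells was set before. The tests of depth took the place of an earlier one, thinning of counts, whose outcome was fixed by its design. The interaction of Rnaseh2b and Xbp1 held 752 genes that differed between backgrounds. With the preset correlation 11 lists were called, and 0 of them kept the call with an estimated correlation. List medians were -0.33 for p53 targets, 0.18 for XBP1 secretory pathway genes, 0.93 for interferon-stimulated genes, 0.92 for antigen presentation and 0.60 for NRF2 targets. They were -0.34 for G2 and mitosis, -0.27 for DNA repair, -0.26 for stem cell, -1.16 for Paneth, -0.62 for goblet and -0.51 for enterocyte markers.

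Single genes with a positive interaction were Xbp1 at 0.99, Isg15 at 3.40, Xist at 7.85, Vsig2 at 5.94, Hpn at 3.28, Amt at 2.50, Sardh at 2.49, Wdfy1 at 2.44, Sptbn2 at 2.42 and Snhg20 at 2.40. Members of lists were Plk3 at 1.14, Fkbp11 at 1.32, Hyou1 at 0.80, Sec61a1 at 0.65, Dhx58 at 1.62, Lgals3bp at 0.93, Irf9 at 1.17, Psmb8 at 1.56 and Tap2 at 1.09. NRF2 targets were Gstm1 at 1.45, Nqo1 at 0.98, Gstm3 at 1.30 and Cbr3 at 1.15. Genes with a negative interaction were Uty at -9.86, Eif2s3y at -9.68, Kdm5d at -9.60, Ddx3y at -7.12, Cubn at -5.27, Slc10a2 at -3.72, Zg16 at -3.68 and Ang4 at -2.98. The p53 targets were Ccng1 at -0.93 and Plk2 at -0.82, and Ddit4l, of the mTORC1 list, was at -1.60. Cell cycle and repair genes were Ccna2 at -0.56, Nusap1 at -0.79, Bub1b at -0.39, Aurka at -0.35, Chek2 at -0.50 and Chek1 at -0.80. Cell type markers were Olfm4 at -2.13, Smoc2 at -0.84, Ccl6 at -1.52, Clca1 at -1.67 and Galnt12 at -0.63. With LW50 libraries alone 33 of these 45 genes were not called, and the 12 called were Xbp1, Sardh, Wdfy1, Uty, Eif2s3y, Kdm5d, Ddx3y, Cubn, Zg16, Ang4, Plk3 and Fkbp11. Vsig2, Hpn and Amt stood at 0.65, 1.23 and 0.38 there (adjusted p = 0.717, 0.235 and 0.493). In 15 of 21 alternatives Vsig2, Amt and Aurka were not called, and in 13 Galnt12 and Slc10a2. Of 100 arrangements of the libraries, 1 gave as many interactions, namely the real one, and the highest other gave 412. Shuffling also turns the effects of each deletion into spread, which leaves few calls. The arrangements are therefore no measure of chance for the interaction. They also do not address sex, title prefix or the floxed Xbp1 allele. For the other comparisons the 10 splits were too few, with 1 split at the real value in each, and the highest other counts were 1, 0, 413, 1088, 6 and 0 against 135, 888, 2769, 3233, 2477 and 2838.

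The p53 targets were higher in the Rnaseh2b knockout than in the floxed control. Sex of the animals and loss of Rnaseh2b cannot be told apart, since the list had a camera adjusted p of 0.0561 between the Rnaseh2b knockout and the Xbp1 knockout, both of males. Single targets went both ways there, with Plk2 at 26.8 against 16 CPM and Cdkn1a at 306 against 425 CPM. The Xbp1 knockout itself had p53 targets raised over the floxed control, which limits that contrast. The shallow library A may be set aside as the cause, as the median stayed at 0.31 without it.

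Rnaseh2b Xbp1 knockout libraries split by title prefix. Spearman's rho between the LW45 libraries was 0.995. The LW50 library had a rho of only 0.974 and 0.973 with them. It was closer to Xbp1 knockout A, B and C, at 0.986, 0.989 and 0.978, and stood at 0.979, 0.983 and 0.978 with the floxed control. Means, SDs and calls of the Rnaseh2b Xbp1 knockout rest on these unlike libraries. Mislabelling of the LW50 library is unlikely to be the cause, as its Rnaseh2b stood at 6.60 CPM, against 13.8 to 17.0 CPM in the Xbp1 knockout. For Paneth markers lower depth may also be set aside, as the other libraries no deeper than it had at most 0.947 times the sum of the deeper libraries of their groups, against 2.04 for the LW50 library. For enterocyte markers a library property that goes with lower depth stays a possible cause. The ratios were 1.55 and 1.62 in those libraries and 1.36 in the LW50 library, and each of them had the highest PC1 of its group, at 59.6, 13.7 and 32.9. The ratios show that the sum and depth went together, not that depth itself raised the sum. A preparation batch marked by the prefix and a difference between animals cannot be told apart, since 0 LW45 libraries of other genotypes exist.

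Interferon-stimulated genes were higher in the Rnaseh2b Trp53 knockout than in the Rnaseh2b knockout, but the list had an adjusted p of 0.0631 with an estimated correlation. Sex is unlikely to be the whole cause, since against the floxed control, of the same sex, 21 of 33 members rose and 0 fell; the list had an adjusted p of 1.67e-15 with the preset correlation and of 0.134 with an estimated correlation. Immune cells in the culture may be set aside, with Ptprc at 0.0608 CPM. A separate series and loss of p53 cannot be told apart, as 0 libraries of other genotypes lacked a prefix. Rnaseh2b RNA was also lower in the Rnaseh2b Trp53 knockout, at 1.63 ± 0.534 CPM against 5.72 ± 1.05 CPM in the Rnaseh2b knockout. This difference cannot be told apart from loss of p53 either.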

How the results depend on the processing

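The smallest group size was 3, sex and title prefix were confounded with some genotypes, and the cause of each shift below was not tested. Some of these fits were chosen after seeing the data: voom with group weights, the fit without 3 libraries, and the 9 libraries with groups alone. Comparisons are named in the order Rnaseh2b knockout with floxed control, Xbp1 knockout with floxed control, then Rnaseh2b Xbp1 knockout with Rnaseh2b knockout, with Xbp1 knockout and with floxed control, Rnaseh2b Trp53 knockout with Rnaseh2b knockout, and interaction. Fitting only the groups compared gave 242 genes for the Rnaseh2b knockout, 795, 235 and 1300 for the Rnaseh2b Xbp1 knockout and 187 for the interaction. DESeq2 gave 265, 1438 and 1528 genes for the Rnaseh2b knockout, the Xbp1 knockout and the interaction. Voom with group weights gave 240, 1369, 1473 and 1587 genes in that order, 4303 for the Rnaseh2b Trp53 knockout and 429 for the interaction. Without the 3 libraries under 11 M counts the counts were 928, 2351, 5712, 6887, 6722, 5213 and 3915. Those libraries were Rnaseh2b knockout A, Xbp1 knockout C and Rnaseh2b Xbp1 knockout A, the only LW50 library of its group. Genotype and title prefix then cannot be told apart in the comparisons of the Rnaseh2b Xbp1 knockout and in the interaction. The same holds for the fits that left out Rnaseh2b Xbp1 knockout A alone. LW50 libraries alone gave 1481, 175 and 809 genes for the Rnaseh2b Xbp1 knockout and 96 interactions. There Alpi stood at -0.48 against the Rnaseh2b knockout and -0.30 against the Xbp1 knockout, and Ccl20 at -1.14 against the floxed control, each opposite to the fit on all libraries. A block by replicate letter, whose letters need not pair, gave 65 and 436 genes for the Rnaseh2b and Xbp1 knockouts, and the same 9 libraries with groups alone gave 223 for the Rnaseh2b knockout. Interferon-stimulated genes in the Rnaseh2b knockout had a median of -0.31 with an estimated correlation (adjusted p = 0.772) and with fry (adjusted p = 0.55), -0.34 with the block (0.0606) and -0.35 for the 9 libraries (0.0533). The p53 list in the interaction had -0.33 with an estimated correlation (adjusted p = 0.24). Leaving out each library gave counts of 72 to 112, 308 to 945, 1532 to 4027, 1437 to 5353, 1231 to 4292, 1514 to 2483 and 200 to 2993. The interferon median in the Rnaseh2b knockout ran from -0.46 to -0.08. Of 451 named called results, 192 kept their call and direction under every alternative and 3 reversed in direction. The size of the change was not compared.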

Other observations

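Added comparisons here were those of the Rnaseh2b Trp53 knockout with the floxed control and of the Rnaseh2b knockout with the Xbp1 knockout. These and the test of genes beside Xbp1 were chosen only after the result was seen. The Rnaseh2b Trp53 knockout and the floxed control were of the same sex, and p53 targets were lower there. Cdkn1a fell by 2.06 (SE 0.10, edgeR adjusted p = 2.08e-08), Phlda3 fell by 4.57 (SE 0.29) and Gdf15, a stress-induced cytokine, fell by 3.22 (SE 0.30). Of 34 p53 targets 17 fell, with an adjusted p of 0.00216 with an estimated correlation. Of 27 ATF4 targets 22 fell, with an adjusted p of 0.0175 with an estimated correlation, and Asns fell by 0.92 (SE 0.08) and Chac1 fell by 2.38 (SE 0.22). Xaf1, which lies near Trp53, rose by 3.87 (SE 0.36) and Ifitm3 by 1.52 (SE 0.17). In all 3435 genes were called, 1926 without floxed control B, 2138, 2073 and 2162 without Rnaseh2b Trp53 knockout 1, 2 and 3, 7112 with only these groups fitted, 7093 with limma voom and group weights, and 7100 without the 3 libraries under 1.1e7 counts.

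The Rnaseh2b knockout and the Xbp1 knockout were both of males. Ddit4l was higher in the Rnaseh2b knockout by 1.95 (SE 0.22), Eda2r by 1.39 (SE 0.18) and Plk2 by 0.74 (SE 0.12), while Cdkn1a fell by 0.48 (SE 0.10). Clu, a marker of regenerating epithelium, was higher by 2.38 (SE 0.37), and Duox2 fell by 3.40 (SE 0.51). Of 36 XBP1 secretory pathway genes 22 were higher, with an adjusted p of 0.000896 with an estimated correlation. In all 1967 genes were called, 750 and 1082 without Rnaseh2b knockout B and C, 985 without Xbp1 knockout B, 1301 with only these groups fitted, and 4124 without the 3 libraries under 1.1e7 counts. Rnaseh2b Trp53 knockout libraries had less Rnaseh2b than the Rnaseh2b knockout, at 1.63 ± 0.534 against 5.72 ± 1.05 CPM. Xist was at 11.94 CPM in Rnaseh2b knockout A, from 68 counts.

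Within 10 Mb of Xbp1, 5 of 103 tested genes were called between the Rnaseh2b knockout and the floxed control, where 0.81 would fall by chance, with Fisher's exact p = 0.00129. Camk2b, Emid1 and Adcy1 lie 0.449, 0.414 and 1.54 Mb from Xbp1. Camk2b stood at 3.13, 3.48 and 4.71 CPM in the 3 groups with the floxed Xbp1 allele and at 17.9 and 18.7 CPM in the groups without it. Igfbp1 went against this pattern, with 0.198 CPM in the Xbp1 knockout and 2.41 CPM in the floxed control. The same 10 Mb window held 10 called genes in the interaction, with Fisher's exact p = 0.0274. The allele also differs in comparisons without enrichment, namely the Rnaseh2b Xbp1 knockout against the Rnaseh2b knockout (23 called where 18 would fall by chance, Fisher's exact p = 0.19), the Rnaseh2b knockout against the Xbp1 knockout (16 against 13, Fisher's exact p = 0.291) and the Rnaseh2b Trp53 knockout against the floxed control (24 against 22, Fisher's exact p = 0.63). Whether sequence carried with the floxed Xbp1 allele may set the level of some of these genes stays open, and a comparison of floxed and wild-type littermates could test it.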
